A study of Oryza sativa Indica Group and Oryza sativa Japonica Group with 20 samples.

How the data were processed

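Male meiocytes of rice were isolated by micromanipulation from anthers in prophase of the first meiotic division, in the indica cultivar IR64 and in Azucena, per the labels' protocols. The series lists 20 samples in 10 groups of 2. CUT&Tag, in which a tagged transposase is directed to chromatin by an antibody, was used for H3K4me3, a histone mark of active promoters, and for H3K27me3, the mark of Polycomb repression. Whole-genome bisulfite sequencing (BS-seq) covered meiocytes, by a low-input protocol, and flag leaves, from bulk DNA. The analysis used the 8 meiocyte CUT&Tag libraries and the 8 BS-seq libraries. The 4 flag-leaf CUT&Tag samples were not analysed here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate plants, so p-values from permuted libraries measure only the spread between these libraries, which may be technical. The p-values from shifted positions and from permuted chromosomes do not measure spread between libraries at all.

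The deposited peak lists held 1 list per library, with no pooling of replicates visible. Each deposited row gave a score, a fold enrichment at the summit over the local background (a ratio), and the −log10 p and −log10 q of the summit. The lowest −log10 q of the lists lay between 2.01 and 2.03. fastp 0.20.1, Bowtie2, MACS2 2.1.0 and Bismark 0.22.3 were named in the submitters' processing notes, without their roles. The genome builds, the use of a control library and the duplicate filter were not given in the sources used here. A table of the authors gave clean reads, aligned reads, uniquely aligned reads and peak numbers per CUT&Tag library, and its peak numbers equalled the length of each list. A second deposited table gave, per BS-seq library, the mapped reads and the fraction of cytosines detected, defined by the authors as covered at least 4 times, and the fraction of bins of 50 bp past a coverage of 20.

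The IR64 and Azucena lists used different chromosome names and chromosome ends, and the Azucena lists also held unplaced contigs. They were therefore treated as 2 assemblies. Peaks were not overlapped between cultivars and no coordinates were converted. Positions are given in the coordinates of each cultivar's own list, 1-based, with the build not stated. The gene table at hand describes another assembly (Nipponbare, ASM3414082v1). Of the H3K4me3 summits of replicate 1, 28.7% in IR64 and 29.8% in Azucena lay within 1000 bp of a gene end of that table, against 25.5% and 25.7% after 200 shifts along the whole chromosome (p 0.00498 each, the smallest possible). After 200 shifts of 10000 to 100000 bp the shares were 28.7% and 29.0% (p 0.587 and 0.00995), so the excess over nearby positions was at most 1.03-fold. The table was not used, since it belongs to another assembly and this excess was small, and genes, promoters, genomic location and the 26 gene lists fixed before the data were examined were not analysed here. As the rule fixed for that case asks, the 5 reproducible regions of highest mean fold enrichment per mark and cultivar are named by position. The BS-seq table held coverage and no methylation levels, so the planned methylation comparisons were replaced by coverage, a measure chosen after the tables were seen.

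Peak number, median peak width and covered length were compared between marks with a two-sided exact permutation test of the difference of means, with labels permuted within cultivar (36 relabellings, smallest p 0.0556). Cultivars were compared within a mark by the 6 relabellings of 2 against 2 libraries (smallest p 0.333). Peaks of different libraries were called shared at an overlap of at least 1 bp. A reproducible region was a merged region of both replicates that held a peak of each. Chance overlap came from 1000 circular shifts along each chromosome, for which 0.001 is the smallest p. Percentages of regions carry 95% Wilson intervals, which cover counting error only. Contigs were left out of overlaps and densities. Chromosome lengths were taken as the last base called in any library of the cultivar, a lower bound, so the right-hand chromosome end is the end of the last called peak. Correlations across the 12 chromosomes used 100000 permutations.

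The fold enrichment and the p of a peak were also inverted together for the read coverage at the summit and the local background, on the assumption that the caller used a Poisson tail and added 1 to both terms of the fold. Summit coverage came out as a whole number, within 0.05, in 100% of the peaks of each of the 8 libraries. The lowest recurring background was taken as the genome-wide background coverage of a library. The search started at a background of 1, since the tail has a second solution below it. In simulations with floors of 1.8 and 2.5, 100% of 5000 summit coverages were recovered within 0.05. The overlap functions were tested on simulated data with a known planted share. The alternatives tried were a −log10 q of at least 5, a fold enrichment of at least 4, merging peaks within 500 bp, reciprocal overlap of 50%, equal numbers of the strongest peaks, each library left out and the replicate number as a block. Coverage thinning, local shifts, region midpoints and all settings for BS-seq coverage were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.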

Results

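Histone modifications were profiled in male meiocytes of the rice cultivars IR64 and Azucena with 2 CUT&Tag libraries per mark and cultivar. Uniquely aligned reads in the authors' table ranged from 9.22 to 13.71 M (in units of 1000000 reads) in the 4 H3K4me3 libraries. The H3K27me3 libraries held 10.11 and 10.28 M in Azucena, and 47.91 and 9.0 M in IR64. DNA methylation libraries comprised 2 meiocyte and 2 flag-leaf libraries per cultivar, with 15.04 to 25.88 M mapped reads in meiocytes and 33.03 to 39.55 M in flag leaves.

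The first comparison set the called peaks of the active and the repressive mark side by side in meiocytes. H3K4me3 formed more peaks than H3K27me3 in both cultivars. H3K4me3 gave 34150 ± 612 peaks in IR64 and 30698.5 ± 624 in Azucena (SD, n = 2 each), and H3K27me3 gave 11381.5 ± 1764 and 17492.5 ± 185 (SD, n = 2 each). The ratio of the means was 2.25 over both cultivars, 3.00 in IR64 and 1.75 in Azucena. The larger IR64 ratio depended on the setting: with a fold enrichment of at least 4 the ratios were 1.82 in IR64 and 1.89 in Azucena, and after thinning to equal background coverage 1.68 and 1.56. H3K4me3 peaks covered 29.1 ± 1.96 Mb per library and H3K27me3 peaks 12.3 ± 4.56 Mb (SD, n = 4 each). Median peak width was 819.75 ± 13.7 bp for H3K4me3 and 698.25 ± 90.0 bp for H3K27me3 (SD, n = 4 each). The widest peaks did not follow the median in Azucena. Peaks over 2000 bp made up 2.27% of H3K4me3 and 5.45% of H3K27me3 peaks there, against 2.73% and 1.29% in IR64. These are widths of called peaks, and the extent of a mark beyond them was not measured. For all 3 measures of the full lists every H3K4me3 library lay above every H3K27me3 library of its cultivar. The two-sided exact permutation p was 0.0556, the smallest that this design allows. For median width this depended on the setting. The ratio was 1.17 in the full lists and 1.10 with a −log10 q of at least 5 (exact permutation p 0.111). With a fold enrichment of at least 4 it was also 1.10 (exact permutation p 0.333).

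**Figure D1:**
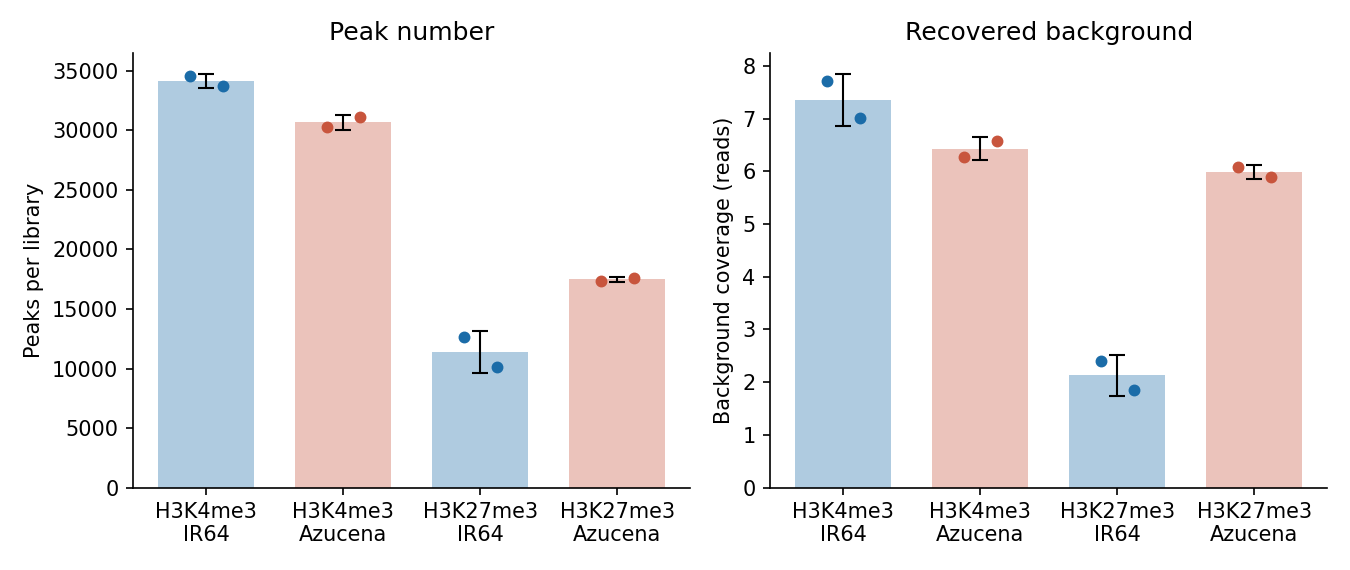
Left, peaks per meiocyte CUT&Tag library. Right, the background read coverage recovered from each peak list. Points are libraries, bars are means and error bars are the SD of 2 libraries. The IR64 H3K27me3 libraries had the fewest peaks, 12629 and 10134, and the lowest background, 2.40 and 1.85 reads.

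The second comparison set the cultivars side by side within each mark. H3K27me3 gave 1.54 times as many peaks in Azucena as in IR64 and covered 16.2 ± 0.183 Mb against 8.46 ± 1.39 Mb (SD, n = 2 each), a ratio of 1.92. Its peaks were also wider in Azucena, with a median of 775.5 ± 14.8 bp against 621 ± 14.1 bp (SD, n = 2 each). Peaks over 2000 bp made up 5.45% ± 0.498 of the Azucena H3K27me3 peaks and 1.29% ± 0.384 of those of IR64 (SD, n = 2 each). H3K4me3 differed less, with an IR64 to Azucena ratio of 1.11 for both peak number and covered length, but the direction depended on the setting. The ratio of peak number was 0.931 with a fold enrichment of at least 4 and 0.985 after thinning to equal background coverage, and that of covered length was 0.971 with the same fold filter. The exact permutation p was 0.333 for each of these differences between the full lists, the smallest that 2 against 2 libraries allow. Median H3K4me3 width was 813 ± 18.4 bp in IR64 and 826.5 ± 6.36 bp in Azucena (SD, n = 2 each), an exact permutation p of 0.667.

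The cultivar difference in H3K27me3 peak number went with a difference in coverage. Background coverage recovered from the H3K27me3 lists was 2.13 ± 0.387 reads in IR64 and 5.99 ± 0.130 in Azucena (SD, n = 2 each), and the median summit coverage was 23.5 and 51 reads. Among peaks with a fold enrichment of at least 4, Azucena had 6260.5 ± 487 and IR64 6060 ± 655 H3K27me3 peaks (SD, n = 2 each), a ratio of 1.03 with an exact permutation p of 0.667. Covered length and median width of these peaks differed, with IR64 to Azucena ratios of 0.669 and 0.657 (exact permutation p 0.333 each, the smallest possible). A fold cutoff does not equalise coverage between libraries, and thinning was applied to peak number only. A width difference apart from coverage was therefore not tested.

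Replicates of each group were then compared peak by peak. Of the H3K4me3 peaks, 87.3% and 91.0% overlapped the other replicate in IR64 and 91.9% and 89.3% in Azucena. H3K27me3 replicates overlapped by 87.5% and 87.4% in Azucena. In IR64, 66.1% of the peaks of replicate 1 overlapped replicate 2, and 83.7% in the other direction. Chance overlap from circular shifts was 3.83% to 15.9%, and each p was 0.001, the smallest that 1000 shifts allow. The base-pair Jaccard index was 69.2% and 70.5% for H3K4me3 in IR64 and Azucena, and 51.5% and 72.1% for H3K27me3. Reproducible regions numbered 29541 for H3K4me3 and 8219 for H3K27me3 in IR64, and 27224 and 14872 in Azucena.

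Part of the H3K27me3 regions of meiocytes overlapped H3K4me3 regions. In IR64, 3721 of 8219 reproducible H3K27me3 regions (45.3%, 95% interval 44.2 to 46.4) overlapped a reproducible H3K4me3 region, against 16.1% by chance, a 2.82-fold excess. In Azucena, 5094 of 14872 regions (34.3%, 33.5 to 35.0) overlapped, against 15.9% by chance, a 2.15-fold excess. Both excesses had the smallest p that 1000 shifts allow, 0.001. Seen from H3K4me3, 12.6% of the IR64 regions and 18.8% of the Azucena regions overlapped H3K27me3. With a reciprocal overlap of 50% the shares were 33.4% and 23.4%, and the excess over chance was 6.93-fold in IR64 and 5.10-fold in Azucena. With the midpoint of the H3K27me3 region inside an H3K4me3 region the excess was 4.74-fold and 3.64-fold. Against nearby positions, from shifts of 10000 to 100000 bp, the excess was lower than against whole-chromosome shifts. It was 2.61-fold in IR64 (17.3% by chance) and 1.95-fold in Azucena (17.6% by chance). These libraries were made from many cells, and an overlap does not show that 1 nucleosome or 1 cell carried both marks. Signal of open H3K4me3 sites entering the H3K27me3 libraries could also give overlaps, and it was not excluded as a part of them in either cultivar.

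The share of H3K27me3 regions with H3K4me3 rose with H3K27me3 fold enrichment. From the lowest to the highest quintile it went from 32.8% (95% interval 30.6 to 35.2) to 58.9% (56.5 to 61.2) in IR64 and from 18.6% (17.2 to 20.0) to 49.7% (47.9 to 51.5) in Azucena. The reverse relation differed between cultivars. Over the H3K4me3 quintiles, the share with H3K27me3 went from 7.73% (7.08 to 8.44) to 16.3% (15.4 to 17.3) in IR64. In Azucena it was 18.1% (17.1 to 19.1) in the lowest quintile, 21.6% in the next, and 14.9% (13.9 to 15.8) in the highest. H3K27me3 regions with H3K4me3 had a median width of 1048 bp in IR64 and 1220 bp in Azucena, against 848 and 910 bp for those without.

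**Figure D2:**
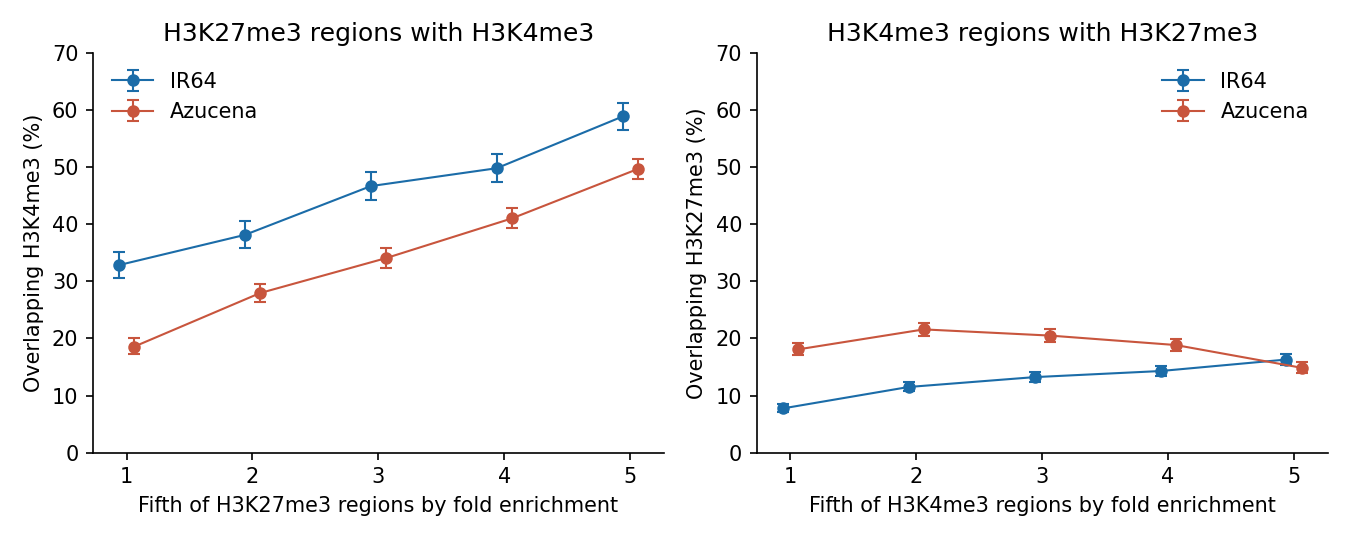
Share of reproducible regions of one mark that overlap the other mark (%), by quintile of fold enrichment from lowest (1) to highest (5). Bars are 95% Wilson intervals, and the H3K27me3 panel rises in both cultivars while the H3K4me3 panel rises only in IR64, from 7.73% to 16.3%.

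Peak density differed between chromosomes, and for H3K4me3 in much the same way in both cultivars. Chromosome 3 was densest, at 106 ± 0.868 H3K4me3 peaks per Mb in IR64 and 98.5 ± 1.91 in Azucena, followed by chromosomes 1 and 2 (SD, n = 2 each). Chromosome 11 was sparsest, at 71.2 ± 1.47 and 62.6 ± 1.71 peaks per Mb (SD, n = 2 each). Across the 12 chromosomes the cultivars' H3K4me3 densities had r = 0.992 and rho = 0.951 (permutation p 1e-05 and 3e-05, adjusted over 4 relations 4e-05 and 0.00012), and r = 0.983 without chromosomes 1 and 3. H3K27me3 densities had r = 0.525 and rho = 0.517 (permutation p 0.0901 and 0.0885, adjusted 0.12 and 0.118), and r = 0.67 without chromosomes 1 and 11. Within a cultivar the 2 marks had r = 0.636 in Azucena (permutation p 0.0226, adjusted 0.0451; rho = 0.615, p 0.0363, adjusted 0.0727), which fell to 0.394 without chromosomes 1 and 3, so it rests on those. In IR64 r was -0.177 and rho -0.203 (permutation p 0.602 and 0.527, adjusted 0.602 and 0.527), and r was -0.437 without the same pair. Chromosomes are not independent replicates.

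**Figure D3:**
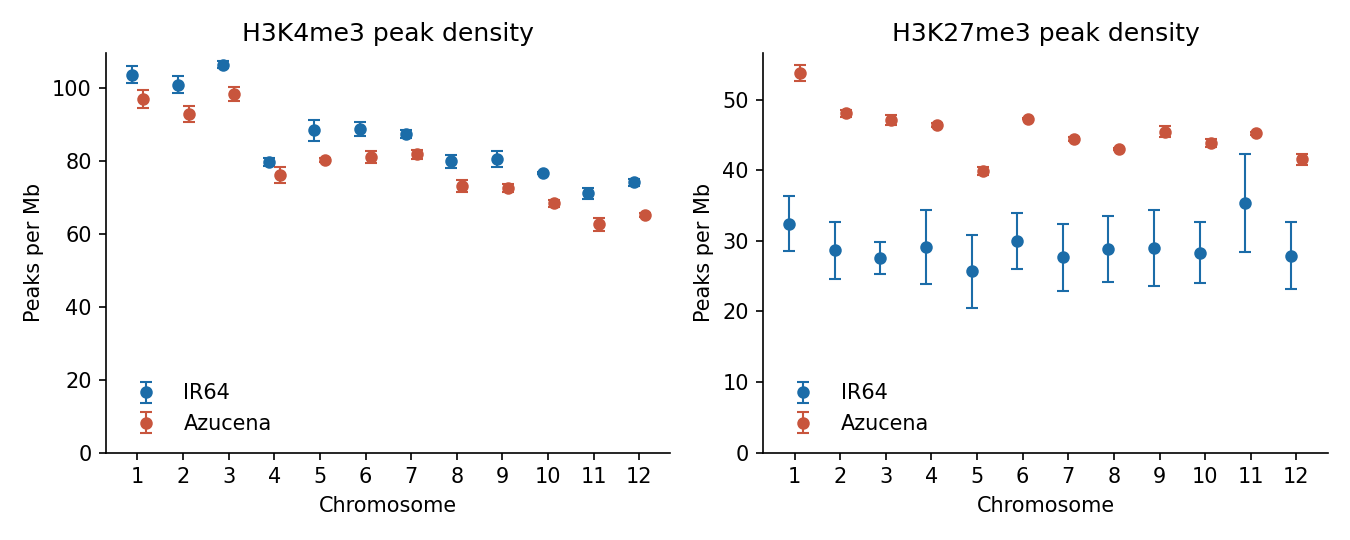
Peaks per Mb on the 12 chromosomes (x axis) for each mark and cultivar. Points are means and error bars the SD of 2 libraries, and H3K4me3 is densest on chromosome 3 and sparsest on chromosome 11 in both cultivars.

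The number of H3K27me3 peaks per H3K4me3 peak was higher in the bins sparsest in H3K4me3 than in the densest. In IR64, bins of 1000000 bp in the lowest H3K4me3 quintile held 52.8 H3K27me3 peaks per 100 H3K4me3 peaks, against 23.7 in the highest. In Azucena the quintiles from lowest to highest held 66.8, 62.2, 69.2, 54.3 and 46.1, with no steady fall over the sparser ones. Yet the 2 marks were positively correlated across bins, with a Spearman rho of 0.392 and 0.488 in the 2 IR64 replicates (383 bins) and 0.639 and 0.644 in Azucena (375 bins). The joint rise lay in the sparser quintiles. From the lowest to the highest H3K4me3 quintile, bins held a mean of 19.0, 26.6, 33.7, 33.2 and 32.1 H3K27me3 peaks in IR64. In Azucena they held 23.6, 36.6, 55.6, 56.9 and 56.5. Bins are not independent replicates, and the quintile ratios share the H3K4me3 counts that define the quintiles, so part of the fall is built in.

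The regions of highest fold enrichment were few and often called in both marks. Folds are the authors' and serve here to rank regions within a list. The strongest IR64 H3K27me3 regions were chromosome 4, 15303372 to 15303921 (mean fold 30.8 ± 0.566), chromosome 7, 7 to 422 (29.3 ± 0.312), chromosome 1, 34427918 to 34428352 (23.0 ± 0.588), chromosome 12, 18044720 to 18045223 (22.5 ± 0.215) and chromosome 9, 1723128 to 1723870 (21.0 ± 1.73) (SD, n = 2 replicates). The strongest IR64 H3K4me3 regions were chromosome 9, 1723139 to 1723874 (24.4 ± 0.488), chromosome 7, 17 to 416 (18.2 ± 2.98), chromosome 12, 16172937 to 16173474 (14.0 ± 0.151), chromosome 12, 21774351 to 21775193 (13.8 ± 2.34) and chromosome 4, 23533081 to 23534542 (11.6 ± 1.53) (SD, n = 2). All 10 overlapped a reproducible region of the other mark, but the chromosome 7 and chromosome 9 sites stand in both lists, so the 10 are not separate sites. Among the 20 strongest regions, 18 of H3K4me3 and 13 of H3K27me3 overlapped the other mark, against 12.6% and 45.3% of all regions.

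In Azucena the strongest H3K27me3 regions were chromosome 2, 36468051 to 36468324 (mean fold 30.2 ± 0.381), chromosome 6, 31188609 to 31189027 (26.3 ± 0.129), chromosome 3, 38424461 to 38424979 (23.8 ± 0.115), chromosome 2, 32 to 561 (23.6 ± 0.581) and chromosome 8, 13 to 446 (21.3 ± 1.38) (SD, n = 2). The strongest H3K4me3 regions were chromosome 6, 31188613 to 31189030 (24.2 ± 0.554), chromosome 3, 38424480 to 38424977 (23.0 ± 0.765), chromosome 2, 29 to 557 (21.1 ± 0.796), chromosome 8, 11 to 429 (17.8 ± 0.346) and chromosome 11, 12509691 to 12510616 (11.7 ± 0.805) (SD, n = 2). Of these 10, the first chromosome 2 region was the only one without a reproducible region of the other mark. The sites on chromosomes 6, 3 and 8 and at the start of chromosome 2 stand in both lists, so the 10 are not separate sites. Among the 20 strongest regions, 12 of H3K4me3 and 19 of H3K27me3 overlapped the other mark, against 18.8% and 34.3% of all regions. All 5 named H3K27me3 regions and 4 of the 5 named H3K4me3 regions lay within 1000 bp of the start of a chromosome or of its last called base. The median local background of peaks at such ends was higher than elsewhere in each of the 8 libraries.

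The BS-seq libraries were compared for coverage, meiocytes against flag leaves. Tissue and protocol differ together here, low input for meiocytes and bulk DNA for flag leaves, so they cannot be told apart. Flag-leaf libraries detected 79.2% ± 1.07 of cytosines in IR64 and 77.3% ± 2.99 in Azucena, and meiocyte libraries 38.3% ± 4.17 and 30.3% ± 5.59 (SD, n = 2 each). Over both cultivars the share was 78.3% against 34.3%, a 2.29-fold difference, and usable bins of 50 bp were 73.4% against 31.4%. With labels permuted within cultivar the two-sided exact p was 0.0556 for both, the smallest that this design allows (0.0741 adjusted over 4 measures). Flag-leaf libraries also had 1.84 times as many mapped reads. Per mapped read, flag-leaf libraries detected 3.40 ± 0.0367 cytosines in IR64 and 3.6 ± 0.262 in Azucena, and meiocyte libraries 3.72 ± 0.349 and 2.15 ± 0.0698 (SD, n = 2 each). The flag-leaf to meiocyte ratio was 0.912 in IR64 and 1.68 in Azucena, on opposite sides of 1, and this difference was not tested. Detected cytosines cannot exceed all cytosines, and flag-leaf libraries lay nearer that limit with more reads. The value per read therefore does not compare the tissues at equal depth. Over both cultivars the values were 3.50 and 2.94, a ratio of 1.19 with an exact permutation p of 0.333 (0.333 adjusted). Between the meiocytes of the 2 cultivars the exact permutation p was also 0.333, the smallest possible.

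**Figure D4:**
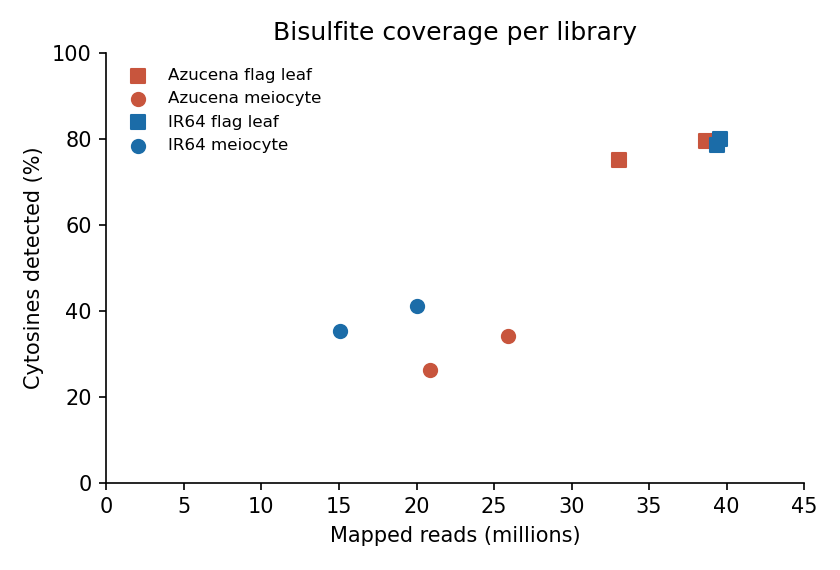
Share of cytosines detected (%) against mapped reads for the 8 BS-seq libraries, circles for meiocytes and squares for flag leaves. Each point is 1 library, and the meiocyte libraries lie between 26.3% and 41.2%, below the flag-leaf libraries at 75.2% to 80.0%.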

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

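Chromosome densities were set over the density of all 12 chromosomes, and chromosomes were listed where both replicates of one cultivar lay above 1 and both of the other below it. For H3K27me3, chromosome 11 lay at 1.201 in IR64 and 0.985 in Azucena, chromosome 2 at 0.979 and 1.05, and chromosome 3 at 0.945 and 1.03. For H3K4me3, chromosome 7 lay at 0.993 in IR64 and 1.01 in Azucena. These differences between cultivars were not tested, and the lengths behind the densities are lower bounds.

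4 measures per library differed in opposite directions in the 2 cultivars, with no overlap between the compared libraries of a cultivar. The share of peaks over 2000 bp in H3K4me3 was 2.12 times that in H3K27me3 in IR64 and 0.416 times in Azucena. For median summit coverage the same ratios were 1.79 and 0.775, and for median fold enrichment 0.835 and 1.06. Cytosines detected per mapped read in flag leaves were 0.912 times those of meiocytes in IR64 and 1.68 times in Azucena. These differences between cultivars were not tested.

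The Azucena lists also held peaks on unplaced contigs, which entered no overlap or density. H3K27me3 had 50 and 53 such peaks in replicates 1 and 2, and H3K4me3 had 25 and 50.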

How the results depend on the processing

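Of 138 values recomputed for 17 results, 132 kept their direction, among them all 72 that left out 1 library. Where the compared groups did not overlap, leaving out 1 library could not reverse a ratio, so most of those 72 outcomes were fixed in advance. Permuting labels over all libraries left a ratio unchanged by construction. Some values kept their direction with a large change in size. The H3K27me3 ratio of IR64 to Azucena for peak number went from 0.651 to 0.968 with a fold enrichment of at least 4. The overlap excess went from 2.82 to 6.93 in IR64 and from 2.15 to 5.10 in Azucena with a reciprocal overlap of 50%. With peaks of fold enrichment of at least 4, the IR64 to Azucena ratio of H3K4me3 crossed 1 for peak number (0.931), covered length (0.971) and median width (1.05). The width ratio, 0.984 as reported, also crossed 1 with a −log10 q of at least 5 (1.004) and with peaks within 500 bp merged (1.01). Chosen after seeing the data, thinning every library to the lowest background coverage gave an H3K4me3 peak number ratio of 0.985, an H3K27me3 ratio of 0.913 (0.651 as reported) and an H3K4me3 to H3K27me3 ratio of 1.62 (2.25 as reported). The cause of these crossings was not tested. H3K27me3 with H3K4me3 over chance stayed between 1.95 and 6.93 in all alternatives. Also chosen after seeing the data, the BS-seq ratio of detected cytosines was 2.29 as reported and 1.19 per mapped read (0.912 in IR64 and 1.68 in Azucena), and the cause of this change was not tested. With labels permuted over all libraries, not within cultivar, the ratios 2.29 and 2.34 had an exact permutation p of 0.0286. That is the smallest that 70 relabellings allow.

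With the replicate number as a block the mark ratio of peak number was 2.30 (exact sign-flip p 0.125, the smallest 4 pairs allow) and the IR64 to Azucena ratios were 1.11 for H3K4me3 and 0.647 for H3K27me3. None of the 11 blocked values changed direction, which was fixed in advance wherever the compared groups did not overlap. The labels do not say whether samples with the same replicate number share material. Over 1000000 bp bins, the replicate deviations of the marks had correlations of -0.0545 in IR64 and -0.102 in Azucena. These values cannot decide it, since noise of each library could hide a shared source. The alternatives for methylation, genes and cultivar overlap were not run, and replicate agreement has no value with 1 library.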

Other observations

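Peaks joined over gaps of up to 1000 bp rarely reached 5000 bp in these meiocytes. H3K27me3 formed 9 and 11 such domains in the Azucena replicates and 6 and 1 in those of IR64, and H3K4me3 formed 1 to 3 per library. The longest H3K4me3 domain of both IR64 replicates lay at one place on chromosome 5, from 31019800 to 31026721 in replicate 1 and from 31020744 to 31026580 in replicate 2. This place was close to the last called base of that chromosome, 31028691. Some bins of 1000000 bp held few H3K4me3 peaks, and an Azucena bin was nearly empty of both marks. In Azucena, chromosome 5 from 10000001 to 11000000 held a mean of 8.5 H3K4me3 and 0.5 H3K27me3 peaks, while the IR64 bin with the fewest H3K4me3 peaks, chromosome 11 from 14000001 to 15000000, held 10 H3K4me3 and 12 H3K27me3 peaks (means of 2 replicates).

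Chosen only after the results were seen were the tests of read number, of H3K4me3 signal within each cultivar and of overlap at chromosome ends, the values for chromosome starts alone and the thinning to read number. Thinning to the lowest background was chosen after the peak lists were seen, and its bound was set before its own result. No biological explanation was tested for any pattern. Cultivar and assembly differ together throughout, and so do tissue and protocol in the BS-seq libraries.

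Fewer H3K27me3 peaks were called in IR64 than in Azucena. Read number was argued against, since the IR64 library with the most uniquely aligned reads had 0.727 times the peaks of the lower Azucena library. Azucena libraries thinned to the reads of the other IR64 library kept 1.70 and 1.73 times its peaks. Recovered background per M uniquely aligned reads was 0.0501 and 0.206 in the IR64 H3K27me3 libraries, against 0.602 and 0.574 in Azucena. Similar read numbers thus did not give similar background coverage. After thinning every library to the lowest recovered background, Azucena had 1.10 times the IR64 number, which is consistent with lower usable coverage as a candidate explanation. Thinning may be imprecise: IR64 replicate 1 thinned to the background of replicate 2 kept 1.17 times the peaks called in replicate 2. Whether this came from the thinning or from a difference between these libraries was not tested. A biological difference between the cultivars stays open and untested.

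H3K27me3 regions of higher fold overlapped H3K4me3 more often. Width does not account for it, since H3K27me3 summits lay inside H3K4me3 regions at least 20.4 percentage points more often in the highest than in the lowest fold quintile of each library. Sites of very high coverage do not either, since the rise was at least 24.8 points without regions of a local background over 5 times the floor. The test set in advance for signal of open H3K4me3 sites entering the H3K27me3 libraries asked for a rise, or a fall, over the H3K4me3 quintiles in both cultivars, and a rise was met in 1 of 2, so that explanation cannot be told apart over both, because the cultivars went opposite ways. Split by cultivar after this was seen, the change was 8.57 points in IR64, where the explanation stays open, and -3.21 points in Azucena. The Azucena fall argues against it as the whole cause there, but only as far as H3K4me3 fold measures that signal. It was also not steady, with 18.1% in the lowest quintile, 21.6% in the next and 14.9% in the highest.

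In Azucena, 4 of the 20 strongest H3K4me3 regions and 5 of the 20 strongest H3K27me3 regions lay at chromosome ends, against 1 of 20 for each mark in IR64. The median local background over the floor was higher at ends than elsewhere in 8 of 8 libraries, as the test set in advance asked, but a raised background lowers the fold, so this decides nothing about high folds. In H3K4me3 it was 1.60 to 1.71 over both ends and 4.74 to 23.7 at chromosome starts alone (2 to 4 peaks per library), against 1.46 to 1.48 elsewhere, and right-hand ends are the last called peaks by construction. Of the reproducible H3K27me3 regions at ends in both cultivars, 93.3% (14 of 15) overlapped H3K4me3, against 38.1% elsewhere, but these include the regions that prompted the comparison, so the value decides nothing. Coverage of repeated sequence that does not depend on the antibody cannot be told apart from marking by both, since no sequence was at hand.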
